A study of Mus musculus with 6 samples.

How the data were processed

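RNA from mouse bone marrow-derived dendritic cells, which are antigen-presenting cells grown from bone marrow in culture, was sequenced after 6 h with phosphate-buffered saline (PBS) or with 18 mM lysine. Lysine is a cationic amino acid. There were 3 samples per group from C57BL/6J mice. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with standard Illumina protocols. Whether poly(A) RNA was selected or ribosomal RNA was removed is not given in the sources used here. The labels do not state that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

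The authors deposited a table of TPM, the length-scaled share of each gene in all transcripts, for 55740 gene models, with a column per sample. The design text of the series states that abundances were quantified with RSEM and expressed as TPM. HISAT2, StringTie, RSEM and edgeR, with the genome build GRCm38.p6, are named per the submitters' processing notes. Their roles, versions and settings, the annotation release and the use of strand are not given in the sources used here. The values have 2 decimals and sum to 1000000 in each sample. TPM divides by transcript length and by the total of the sample, so it keeps no sequencing depth. The depth is unknown, no counting error could be given, and a rise of abundant RNAs lowers all others. An exact 0 may be a failed estimate in this unit, so a gene listed at 0 in a group is given by its value in each sample. The columns of the treated group carry the letter K, the 1-letter code of lysine, and were matched by that letter and the replicate number. The columns of the control group carry the word control. The table's gene symbols were used. Gene positions and transcript classes came from the GENCODE M21 annotation of the same GRCm38 assembly, which held 52135 of the 55740 identifiers (93.5%) and 97.5% of those tested.

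The comparison was lysine against PBS over all 6 samples. Since the deposited table holds TPM and no counts, the test fixed for that case was used, limma with an intensity trend (version 3.58.1 in R 4.3.3) on log2(TPM + 1). Genes with at least 1 TPM in at least 3 samples were tested, 12539 in all. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. They are given with their standard error (SE), and TPM values as mean ± SD with n = 3. Tests counted changes in both directions. With 3 samples against 3, an exact permutation test of a single value cannot go below p = 0.1, so the calls rest on the limma model fitted across genes.

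Before the data were examined, 35 gene lists were fixed. They comprised 21 responses that lysine, a change in osmolarity or dendritic cell activation can involve, 2 lists of RNA classes as signs of RNA quality, and 12 lists of markers of cell types found in bone marrow cultures. Each of the 29 lists with at least 5 tested members was tested with limma's camera, which compares the list with all other genes, at a preset inter-gene correlation of 0.01. Its p-values were adjusted over the lists. Camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance in a single direction, were alternatives. Some genes belong to more than 1 list. Older symbols in the lists were matched through the annotation.

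The genes named in the text were also fixed by rule. They were the 6 largest rises and 6 largest falls among changed genes with groups that did not overlap, a mean of at least 5 TPM and a symbol that is not a predicted model, clone or pseudogene. For each response or quality list, they were the members with the smallest adjusted p, up to 3 where the list passed camera and up to 2 otherwise. For each cell type list it was the member with the highest mean. Slc7a1, Slc7a2, Cd40, Cd80, Cd86, Ccr7, H2-Ab1, Il12b, Il6, Tnf, Il1b, Il10 and Cd274 were named whatever their p. Any other gene was chosen after its values were seen, among them members that went against the rest of their list.

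The alternatives chosen before the data were examined were a replicate block, a pseudocount of 0.1, no filter beyond a value above 0, both other list tests, and leaving out each sample in turn. The 5 alternatives added after seeing the data were median-of-ratios scaling, quantile normalization, rescaling to protein-coding nuclear genes, a stricter filter of 5 TPM and limma without the trend. The test was checked on simulated data for this comparison, with 200 of 12539 genes changed. It recovered 26% of the changed genes at a log2 change of 0.5, 84% at 1 and 97% at 2. It made 4, 4 and 13 false calls at these sizes. Genes were simulated independently, and the changed ones were drawn from the more highly expressed. A far larger share of genes changed in the data, so these rates need not hold there. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.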

Results

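Expression was measured by RNA sequencing in cultured mouse bone marrow-derived dendritic cells, in 3 samples given PBS and 3 given 18 mM lysine for 6 h. Between 12277 and 12449 gene models reached 1 TPM in each sample. The depth of the libraries is unknown, because TPM keeps none. Over the genes tested, the Pearson correlation of log2(TPM + 1) was 0.974 to 0.982 between samples of a group and 0.914 to 0.934 between groups. The first principal component held 66.6% of the variance and separated the groups, and the second held 11.6%. At most 0.598% of the tested genes had an identical TPM in a pair of samples of a group, so no library was taken to be deposited more than once.

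The comparison addressed how added lysine changes gene expression in these cells. With lysine, 21 of 27 genes of the amino acid response rose, a list of its transcription factor gene Atf4 and targets of ATF4. The p53 targets, immediate early genes and lysosomal genes were mostly higher as well. Each of these lists passed camera, but not with an estimated correlation (adjusted p = 0.565). Genes of the type I interferon response fell in 27 of 30 cases. In the list of NRF2, the regulator of antioxidant genes, its targets and glutathione genes, 18 of 25 fell. Glycolytic and HIF1 target genes fell in 18 of 26 cases. Among genes of cholesterol synthesis 12 of 23 fell. Among genes of dendritic cell surface molecules Cd80, Cd86 and Cd274 rose, Cd40 fell, and Ccr7 and H2-Ab1 did not pass the test.

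Of the 12539 genes tested, 6904 (55.1%) changed, 3231 of them higher and 3673 lower with lysine. At least 2-fold changes were found for 1633 genes, 787 higher and 846 lower. The groups did not overlap for 7944 genes (63.4%), where chance gives 10%. At an unadjusted p under 0.05 there were 7611 genes. The median log2 fold change of all tested genes was -0.05.

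**Figure D1:**
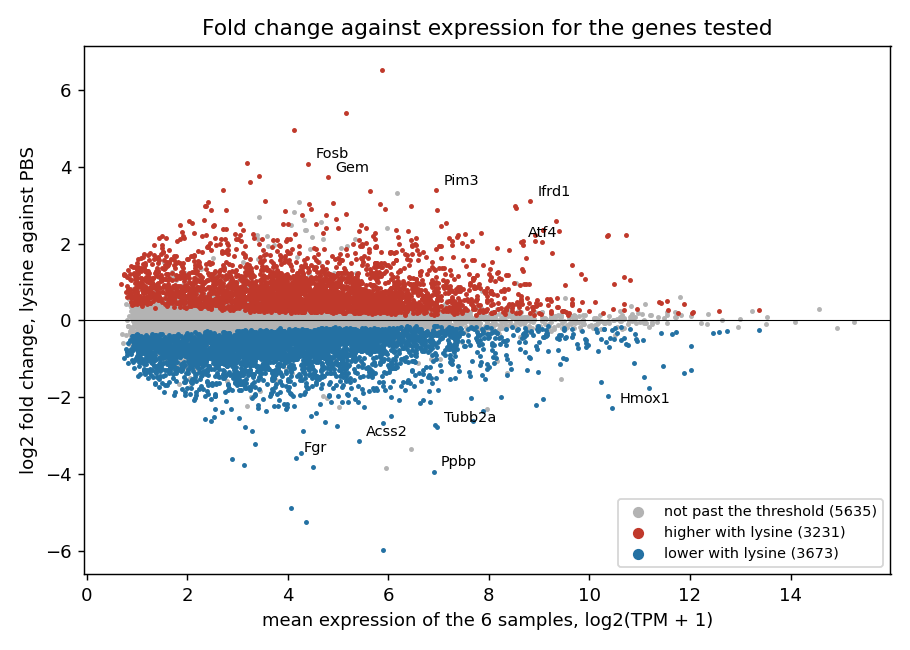
Each point is a tested gene. The x axis is log2(mean TPM + 1), with the mean taken over the 6 samples. The y axis is the log2 fold change, lysine against PBS. Red points are the 3231 genes higher and blue points the 3673 genes lower with lysine, and grey points did not pass the test, with Fosb near 4 and Ppbp near -4 on the y axis.

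Fosb, a subunit of the AP-1 transcription factor, rose from 1.37 ± 0.105 to 39.0 ± 2.28 TPM, a 28.5-fold change (log2 fold change 4.08 ± 0.087, adjusted p = 3.1e-06). It lies on chromosome 7, 19302696 to 19310051 in GRCm38 (ENSMUSG00000003545). Gem, a small GTP-binding protein that regulates calcium channels, rose from 2.77 ± 0.269 to 50.8 ± 16.7 TPM (log2 fold change 3.72 ± 0.25, adjusted p = 8.68e-05; chromosome 4, 11704457 to 11714752). The other rises that the rule named were short non-coding RNAs, each listed at 0 in all 3 PBS samples. The lysine samples held 44.92, 71.76 and 230.39 TPM of a 5S ribosomal RNA model (adjusted p = 0.000175) and 22.28, 169.6 and 17.66 TPM of another (adjusted p = 0.00158). They held 20.49, 16.33 and 12.16 TPM of the brain cytoplasmic RNA Bc1 (adjusted p = 2.82e-05; chromosome 7, 144914470 to 144914637) and 10.69, 3.98 and 18.67 TPM of an Rmrp model, the RNA of a mitochondrial RNA-processing enzyme (adjusted p = 0.00115; chromosome 4, 43492783 to 43493063). Such models are short and have near-identical copies, so these values are uncertain. The largest further rises among protein-coding genes, chosen after their values were seen, were Pim3, a serine/threonine kinase (20.7 ± 1.21 to 226 ± 19.5 TPM), the histone gene H4c17 (7.62 ± 1.81 to 89.8 ± 26.6 TPM), Ifrd1 (93.9 ± 4.84 to 812 ± 19.6 TPM) and Irs2, an adaptor of insulin signalling (5.43 ± 0.783 to 52.5 ± 7.04 TPM). Their adjusted p-values were 5.03e-06, 0.000129, 3.1e-06 and 2.63e-05.

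Among the falls, Ppbp, a platelet chemokine also made by myeloid cells, dropped from 223 ± 15.0 to 13.6 ± 1.996 TPM (16.4-fold lower, log2 fold change -3.94 ± 0.11, adjusted p = 6.88e-06; chromosome 5, 90768518 to 90770063). Tifab, an inhibitor of TRAF signalling, fell from 41.3 ± 14.7 to 1.93 ± 0.649 TPM (log2 fold change -3.82 ± 0.26, adjusted p = 9.34e-05; chromosome 13, 56173704 to 56178885). The Src-family kinase Fgr fell from 32.0 ± 4.64 to 1.78 ± 0.4996 TPM (log2 fold change -3.57 ± 0.16, adjusted p = 2.77e-05; chromosome 4, 132974095 to 133001910). Dhx58, which encodes the RNA sensor LGP2, fell from 17.4 ± 2.56 to 0.973 ± 0.270 TPM (log2 fold change -3.22 ± 0.15, adjusted p = 3.06e-05; chromosome 11, 100694884 to 100704271). Acss2, which makes acetyl-CoA from acetate, fell from 75.5 ± 5.68 to 7.74 ± 1.78 TPM (log2 fold change -3.14 ± 0.15, adjusted p = 3e-05; chromosome 2, 155517948 to 155585724). The small nuclear RNA Rnu11 was listed at 58.5, 24.56 and 34.79 TPM in the PBS samples and at 0 in all 3 lysine samples (adjusted p = 5.04e-05; chromosome 4, 132270080 to 132270213).

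In the amino acid response list, 21 of 27 tested members rose, 1 fell and 5 did not pass, with the same 21 and 1 adjusted over the list alone. The median log2 fold change was 1.32. Camera gave adjusted p = 1.43e-08 for the list, and adjusted p = 0.565 with an estimated correlation. Atf4 itself rose from 155 ± 6.16 to 637 ± 28.6 TPM (log2 fold change 2.04 ± 0.057, adjusted p = 6.88e-06). Ppp1r15a, which directs the dephosphorylation of the translation factor eIF2alpha, rose from 58.4 ± 2.44 to 275 ± 13.4 TPM, and Sesn2, an inhibitor of mTORC1, from 17.8 ± 0.551 to 74.6 ± 0.982 TPM (both adjusted p = 6.88e-06). The member that fell was the cystine transporter Slc7a11 (log2 fold change -0.64 ± 0.11), which the NRF2 list also holds.

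Genes that transport or use cationic amino acids went both ways. Of 21 tested, 6 rose, 9 fell and 6 did not pass, against 6 and 10 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.446). Slc7a1, a transporter of lysine and arginine, rose from 6.09 ± 0.403 to 18.4 ± 1.77 TPM (log2 fold change 1.45 ± 0.098, adjusted p = 8.72e-05). Slc7a2, another such transporter, rose from 174 ± 35.0 to 252 ± 41.9 TPM (adjusted p = 0.0446), but this call was lost in 7 alternatives, with adjusted p from 0.0586 to 0.127. These include leaving out PBS replicate 2 (0.0642) or 3 (0.0941) and lysine replicate 1 (0.124) or 2 (0.127). Odc1, the first enzyme of polyamine synthesis, rose from 77.0 ± 3.99 to 298 ± 12.1 TPM (log2 fold change 1.94 ± 0.06), and Arg1, which splits arginine into ornithine and urea, fell from 868 ± 61.4 to 212 ± 33.4 TPM (log2 fold change -2.04 ± 0.12).

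Of 23 p53 targets and apoptosis genes, 14 rose, 5 fell and 4 did not pass, with the same 14 and 5 adjusted over the list alone (median log2 fold change 0.54; camera adjusted p = 0.00292; adjusted p = 0.565 with an estimated correlation). Mdm2, the ubiquitin ligase of p53, rose from 185 ± 4.91 to 776 ± 41.8 TPM (log2 fold change 2.06 ± 0.056, adjusted p = 6.88e-06). Bbc3, which encodes the pro-apoptotic protein PUMA, rose from 17.0 ± 1.22 to 70.1 ± 4.999 TPM. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 434 ± 17.2 to 1174 ± 105 TPM. Members that fell included Casp8, which encodes a protease of apoptosis (-1.14), Bad (-0.82), Bid (-0.28) and Sesn1 (-0.54), given as log2 fold changes.

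Immediate early genes, which cells induce quickly after a stimulus, rose in 15 of 24 cases, fell in 4 and did not pass in 5, with the same 15 and 4 adjusted over the list alone. The median log2 fold change was 0.56 and camera gave adjusted p = 0.00303, with adjusted p = 0.565 with an estimated correlation. Junb, another AP-1 subunit, rose from 223 ± 19.2 to 1117 ± 87.5 TPM (log2 fold change 2.32 ± 0.086, adjusted p = 1.86e-05), and the nuclear receptor Nr4a3 from 9.23 ± 0.221 to 30.4 ± 2.15 TPM (log2 fold change 1.62 ± 0.077). The 4 that fell were Myc (-1.63), Klf2 (-1.36), Egr2 (-0.70) and Egr3 (-1.04), given as log2 fold changes.

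The lysosome list held 33 tested genes, of which 21 rose, 4 fell and 8 did not pass, against 22 and 5 adjusted over the list alone. Camera gave adjusted p = 0.000253 at a median log2 fold change of 0.41, and adjusted p = 0.565 with an estimated correlation. Flcn rose from 34.9 ± 2.32 to 106 ± 2.91 TPM and its partner Fnip1 from 15.8 ± 0.707 to 48.6 ± 3.16 TPM, genes whose products control the transcription factors of lysosomal genes (log2 fold changes 1.57 ± 0.067 and 1.56 ± 0.075). Npc1, a lysosomal cholesterol transporter, rose from 94.2 ± 0.321 to 175 ± 5.97 TPM. The 4 members that fell were the transcription factors Mitf (-0.71) and Tfe3 (-0.76) and the lysosomal enzymes Neu1 (-0.26) and Sgsh (-0.51), given as log2 fold changes. Among the members that rose was the transcription factor Tfeb, from 19.6 ± 3.53 to 36.2 ± 6.18 TPM (log2 fold change 0.86 ± 0.16, adjusted p = 0.00418).

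**Figure D2:**
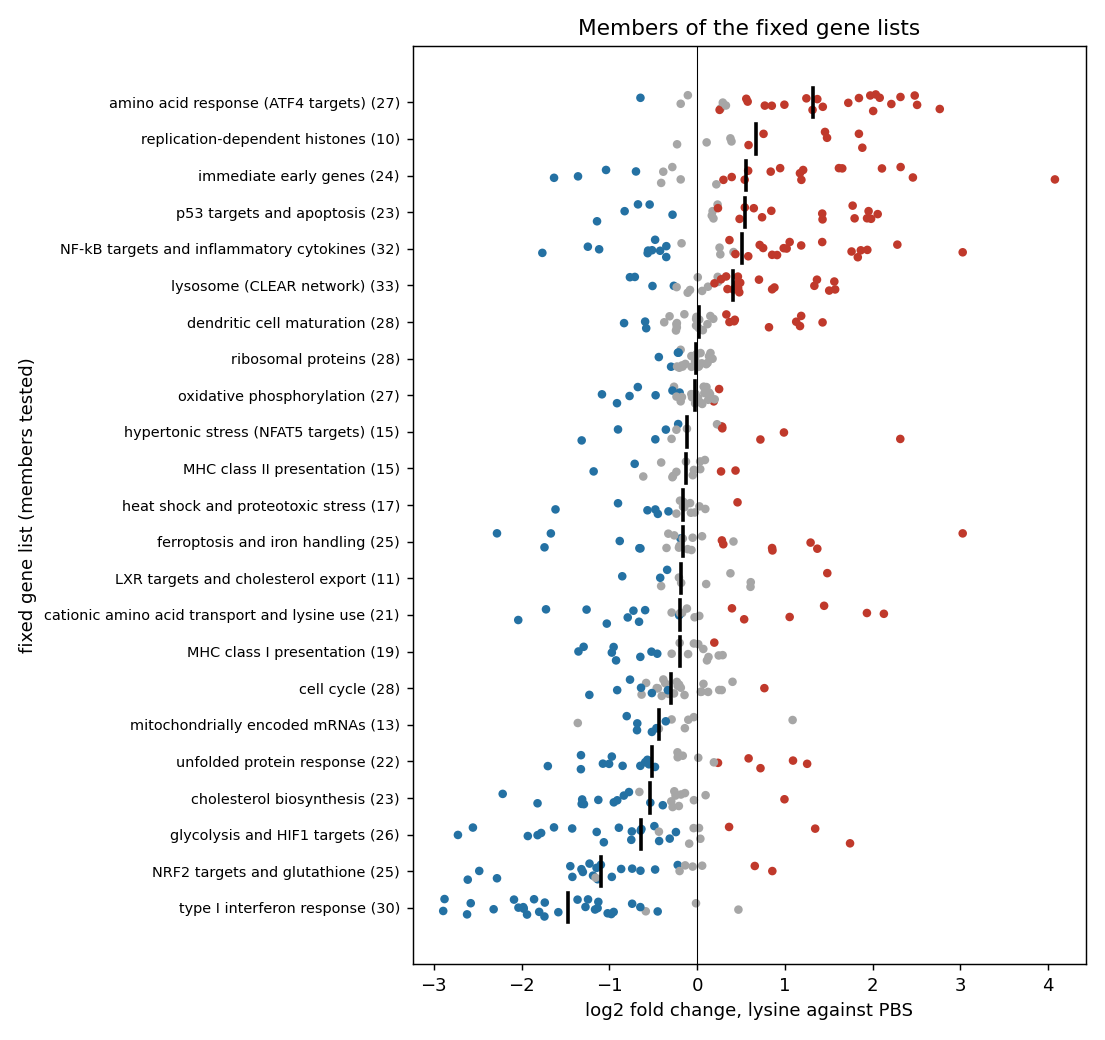
Log2 fold changes, lysine against PBS, of the tested members of each fixed response and quality list, with the number tested in brackets. Each point is a gene, red where higher, blue where lower and grey where the test was not passed, and black bars are medians. The interferon list has the lowest median (-1.47) and the amino acid response list the highest (1.32).

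Type I interferon response genes formed the lowest list, with 27 of 30 tested members lower, 0 higher and 3 not passed, and the same counts adjusted over the list alone. The median log2 fold change was -1.47. Camera gave adjusted p = 1.32e-09, and adjusted p = 0.565 with an estimated correlation. Trim30a fell from 30.9 ± 0.284 to 7.80 ± 0.426 TPM (log2 fold change -1.86 ± 0.071, adjusted p = 2.02e-05) and the antiviral gene Oasl2 from 33.8 ± 3.64 to 3.72 ± 0.866 TPM (log2 fold change -2.89 ± 0.16, adjusted p = 5.04e-05). Macrophage and monocyte markers were lower beside this list, in 6 of 14 and 4 of 8 tested cases. Without lysine replicate 3, 1 interferon gene was called higher.

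NRF2 targets and glutathione genes fell in 18 of 25 cases, rose in 2 and did not pass in 5, against 19 and 2 adjusted over the list alone. The median log2 fold change was -1.10 (camera adjusted p = 9.38e-06; adjusted p = 0.565 with an estimated correlation). Hmox1, which degrades haem, fell from 2321 ± 34.1 to 477 ± 17.4 TPM (log2 fold change -2.28 ± 0.048, adjusted p = 3.1e-06). The quinone reductase Nqo1 fell from 112 ± 18.0 to 19.0 ± 0.599 TPM and the biliverdin reductase Blvrb from 479 ± 39.0 to 178 ± 5.99 TPM. Both rises were Nfe2l2, which encodes NRF2 itself (0.66 on the log2 scale), and Osgin1 (0.86); 1 gene was called higher without PBS replicate 1, 2 or 3 or lysine replicate 2. Of 25 genes of ferroptosis and iron handling 7 rose, 7 fell and 11 did not pass, against 7 and 9 adjusted over the list alone (camera adjusted p = 0.621). Alox5, which makes leukotrienes and belongs to that list with Hmox1, fell from 51.2 ± 3.44 to 14.6 ± 0.0503 TPM.

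In the glycolysis and HIF1 target list, 18 of 26 tested genes fell, 3 rose and 5 did not pass, against 19 and 3 adjusted over the list alone. Its median log2 fold change was -0.64 (camera adjusted p = 0.000295; adjusted p = 0.565 with an estimated correlation). The lactate exporter Slc16a3 fell from 209.8 ± 19.3 to 30.8 ± 0.740 TPM (log2 fold change -2.72 ± 0.078, adjusted p = 7.52e-06) and Ankrd37 from 12.9 ± 1.07 to 1.37 ± 0.220 TPM. Against these, the angiogenic factor Vegfa rose from 278 ± 10.3 to 935 ± 47.5 TPM (log2 fold change 1.74 ± 0.058, adjusted p = 1.32e-05). Also higher were Ndrg1 (1.35 on the log2 scale) and Ero1a (0.37). Oxidative phosphorylation genes rose in 2, fell in 7 and did not pass in 18 of 27 cases, against 2 and 6 adjusted over the list alone (camera adjusted p = 0.604). Sdhb, a subunit of succinate dehydrogenase, fell from 88.7 ± 11.1 to 41.5 ± 6.81 TPM and the electron carrier Cycs from 36.4 ± 2.11 to 20.9 ± 0.147 TPM. Without PBS replicate 1, 1 gene of that list was called higher, and without PBS replicate 3 there were 5. The balance of these calls depended on the scaling, with 7 higher and 6 lower under median-of-ratios scaling and 2 higher and 11 lower under quantile normalization.

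Of 23 genes of cholesterol biosynthesis 12 fell, 1 rose and 10 did not pass, with the same 12 and 1 adjusted over the list alone. The median log2 fold change was -0.53 (camera adjusted p = 0.0106; adjusted p = 0.777 with an estimated correlation). Mvk, the mevalonate kinase, fell from 12.2 ± 4.11 to 2.64 ± 0.432 TPM (log2 fold change -1.82 ± 0.23, adjusted p = 0.000844). The member that rose was Insig1, which holds back the pathway's activator (23.04 ± 4.73 to 46.4 ± 1.496 TPM). Among 11 LXR targets and cholesterol export genes 1 rose, 3 fell and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.964). The median (-0.18) and the mean (0.071) of that list differed in sign, and 3 were called higher without PBS replicate 3 or lysine replicate 3, and 2 under median-of-ratios scaling. The cholesterol exporter Abcg1 rose from 28.0 ± 1.79 to 80.1 ± 5.76 TPM, and Srebf1, an activator of lipid synthesis, fell from 31.1 ± 1.11 to 24.3 ± 1.21 TPM.

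The unfolded protein response list was mixed. Of 22 tested, 12 fell, 5 rose and 5 did not pass, against 13 and 5 adjusted over the list alone (median log2 fold change -0.51; camera adjusted p = 0.0247; adjusted p = 0.565 with an estimated correlation). Without PBS replicate 2 the list missed the threshold (adjusted p = 0.0513). The genes of chaperones and folding enzymes of the endoplasmic reticulum Sdf2l1 (138 ± 3.34 to 41.9 ± 2.62 TPM), Pdia6 (240.1 ± 13.3 to 95.3 ± 3.46 TPM) and Calr (943 ± 13.1 to 481 ± 28.7 TPM) fell. The 5 that rose were the stress sensor Ern1 (1.26), Dnajb9 (1.09), Herpud1 (0.72), Sel1l (0.59) and Edem1 (0.24), given as log2 fold changes. Of 17 heat shock genes 6 fell, 1 rose and 10 did not pass, against 5 and 1 adjusted over the list alone (camera adjusted p = 0.12). Hspa8, the constitutive HSC70 chaperone, fell from 1806 ± 106 to 589.8 ± 34.2 TPM, and Hsp90aa1 rose from 141 ± 2.87 to 195 ± 10.9 TPM.

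Hypertonic stress genes, targets of NFAT5, split evenly, with 5 of 15 higher, 5 lower and 5 not passed, the same adjusted over the list alone (camera adjusted p = 0.69). Their median was -0.12 and their mean 0.080, and the median was 0.0033 under quantile normalization. Without PBS replicate 2 or lysine replicate 2, 3 were called lower. Slc38a2, an amino acid transporter that ATF4 also regulates, rose from 27.2 ± 0.788 to 139 ± 6.71 TPM (log2 fold change 2.32 ± 0.06, adjusted p = 6.47e-06), and the chaperone Hspa4l from 11.3 ± 1.46 to 23.4 ± 1.36 TPM.

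NF-kB targets and inflammatory cytokines rose in 18 of 32 cases, fell in 10 and did not pass in 4, with the same 18 and 10 adjusted over the list alone. The list did not pass camera (adjusted p = 0.0507, median log2 fold change 0.51); it passed in 7 of 14 other settings, which ranged from 0.00285 to 0.12. The NF-kB subunits Rel (17.5 ± 0.805 to 70.2 ± 3.74 TPM) and Relb (59.8 ± 5.81 to 137 ± 6.80 TPM) rose, as did the cytokine Il6 (17.2 ± 1.76 to 61.3 ± 11.4 TPM; log2 fold change 1.76 ± 0.15, adjusted p = 0.000187). Il12b, a subunit of interleukin-12, rose from 5.12 ± 0.486 to 6.91 ± 0.651 TPM (adjusted p = 0.0265), but the call was lost in 5 alternatives (adjusted p from 0.0647 to 0.086), 4 of them without PBS replicate 2 (0.086) or 3 (0.0656) or lysine replicate 1 (0.0647) or 3 (0.0668). Il1b fell from 89.1 ± 9.01 to 61.0 ± 12.9 TPM (adjusted p = 0.0244), with the call lost in 3 alternatives (adjusted p from 0.0515 to 0.0784), among them without PBS replicate 1 (0.0784) or 3 (0.0515). Tnf was at 141 ± 9.53 TPM with PBS and 196 ± 64.8 TPM with lysine and did not pass (adjusted p = 0.196), but it did without lysine replicate 3 (adjusted p = 0.0013, log2 fold change 0.72). Il10 was below the filter, at 0.4, 0.47 and 0.14 TPM with PBS and 0.81, 0.88 and 0.1 TPM with lysine.

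Of 28 dendritic cell maturation genes 9 rose, 3 fell and 16 did not pass, with the same counts adjusted over the list alone. The list did not pass camera (median log2 fold change 0.022, camera adjusted p = 0.263). Fry passed it (up, fry adjusted p = 0.0245), but fry passed 22 of the 29 lists. The T cell costimulator Cd80 rose from 23.1 ± 0.824 to 64.0 ± 2.24 TPM (log2 fold change 1.43 ± 0.061, adjusted p = 2.43e-05) and Cd274, which encodes the inhibitory ligand PD-L1, from 203 ± 5.11 to 459 ± 32.5 TPM (log2 fold change 1.17 ± 0.065, adjusted p = 5.04e-05). Cd86, another costimulator, rose from 44.2 ± 2.75 to 59.8 ± 7.42 TPM (adjusted p = 0.012), and Cd40 fell from 27.3 ± 3.36 to 17.9 ± 3.09 TPM (adjusted p = 0.0127). The chemokine receptor Ccr7 was at 448 ± 21.1 TPM with PBS and 447 ± 49.9 TPM with lysine (adjusted p = 0.959).

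Antigen presentation genes of MHC class II rose in 2, fell in 2 and did not pass in 11 of 15 cases, against 2 and 1 adjusted over the list alone (camera adjusted p = 0.781), and 1 was called lower without lysine replicate 1 or 2. H2-Ab1, a class II chain, was at 319, 338 and 741 TPM in the PBS samples and 360, 354 and 677 TPM in the lysine samples (adjusted p = 0.946), so replicate 3 was high in both groups. The protease gene Lgmn rose from 442 ± 29.2 to 599 ± 9.54 TPM, and Rfx5, a transcription factor of class II genes, fell from 9.26 ± 1.03 to 3.66 ± 1.45 TPM. Of 19 class I genes 8 fell, 1 rose and 10 did not pass, against 8 and 0 adjusted over the list alone (camera adjusted p = 0.219). Calr and Pdia3, chaperones of the loading complex, had the smallest p of these, and Pdia3 fell from 334 ± 16.4 to 213 ± 2.65 TPM. The gene that rose was B2m (log2 fold change 0.20 ± 0.069); it lost its call without PBS replicate 1 or 2 or lysine replicate 1 or 2, and 3 genes of the list were called higher without PBS replicate 3 or under median-of-ratios scaling and 2 without lysine replicate 3.

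Of 28 cell cycle genes 6 fell, 1 rose and 21 did not pass, against 4 and 0 adjusted over the list alone (camera adjusted p = 0.246). The kinase gene Cdk1 fell from 14.9 ± 1.89 to 5.98 ± 1.95 TPM and the transcription factor gene E2f1 from 10.9 ± 0.925 to 6.62 ± 0.495 TPM. The member that rose was the proliferation marker Mki67 (log2 fold change 0.77 ± 0.24), and the list had 0 rises without PBS replicate 1 or 2 or lysine replicate 1 or 2, and 2 without PBS replicate 3. Ribosomal protein genes did not pass in 24 of 28 cases, with 4 lower and 0 higher, against 3 and 0 adjusted over the list alone (camera adjusted p = 0.621). The medians of this list and of the oxidative phosphorylation list were -0.015 and -0.021, and 0.035 and 0.028 under median-of-ratios scaling. Rpl18 fell from 1244 ± 45.1 to 1014 ± 59.2 TPM and Rps14 from 1569.5 ± 37.6 to 1357 ± 18.9 TPM; the call for Rps14 was lost under quantile normalization (adjusted p = 0.132). Without lysine replicate 3, 10 ribosomal protein genes were called lower, and without PBS replicate 3, 2 were called higher. Ribosomal protein genes were 3 higher and 4 lower under median-of-ratios scaling, 3 higher and 6 lower under quantile normalization, and 1 higher and 4 lower after rescaling to protein-coding nuclear genes. Cell cycle genes were 2 higher and 6 lower under median-of-ratios scaling and 2 higher and 5 lower under quantile normalization.

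**Figure D3:**
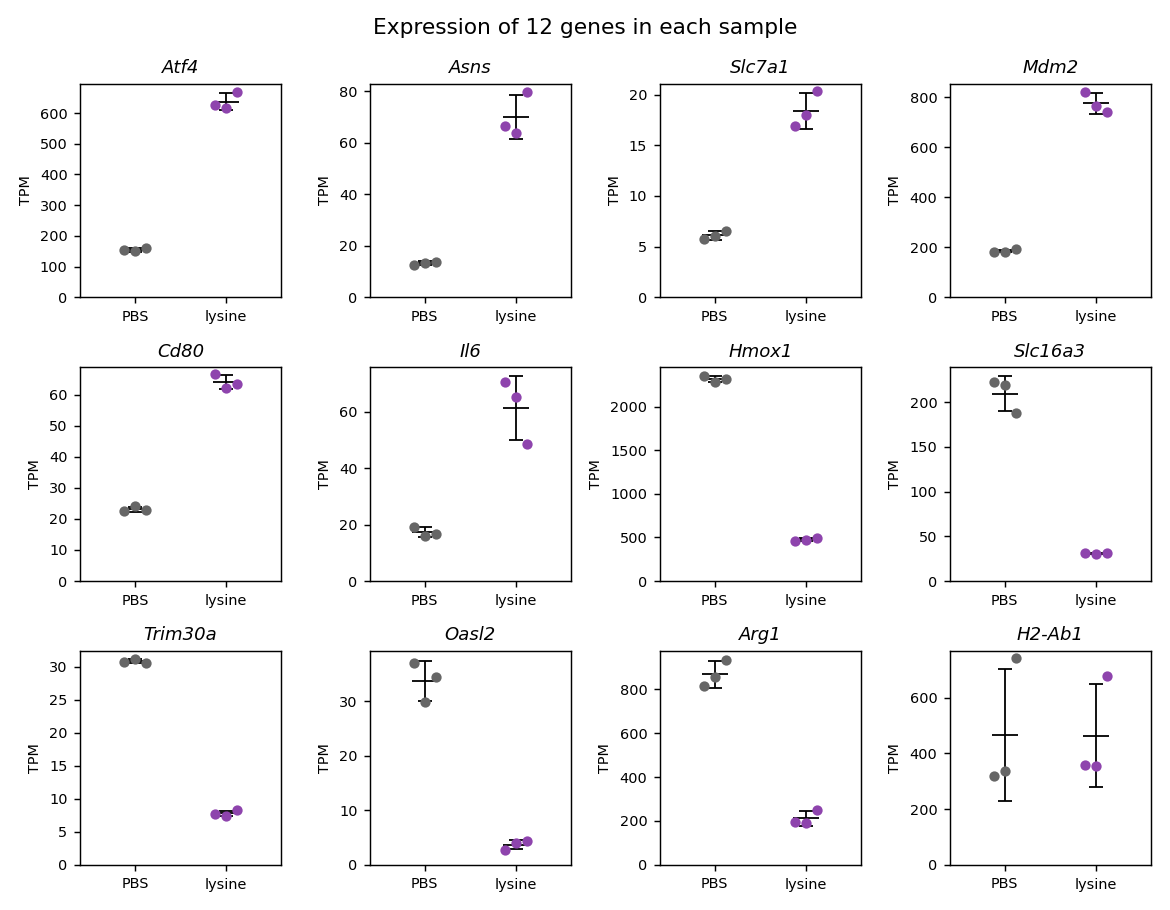
TPM of 12 genes in each sample, with PBS in grey and lysine in purple, and the mean ± SD of 3 samples in black. The groups do not overlap for any gene shown except H2-Ab1, whose values range from 319 to 741 TPM with PBS and 354 to 677 TPM with lysine.

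Among the signs of RNA quality, replication-dependent histone mRNAs, which lack a poly(A) tail, rose in 6 of 10 cases and fell in 0, with 4 not passed and the same counts adjusted over the list alone. Camera gave adjusted p = 0.0133 at a median log2 fold change of 0.67, and adjusted p = 0.565 with an estimated correlation. The call was lost with the stricter filter of 5 TPM (adjusted p = 0.127). H1f2 rose from 120.3 ± 5.12 to 450.0 ± 69.0 TPM and H1f5 from 0.367 ± 0.325 to 3.87 ± 0.854 TPM. H3c14 was listed at 0, 0.15 and 0 TPM in the PBS samples and at 1.81, 1.67 and 2.34 TPM in the lysine samples (adjusted p = 0.000406). Of 13 mRNAs encoded by the mitochondrial genome, 6 fell, 0 rose and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0174; adjusted p = 0.565 with an estimated correlation; adjusted p = 0.0815 without lysine replicate 1, where 1 was called higher). They included mt-Nd1 (2533 ± 27.9 to 1773 ± 34.2 TPM), mt-Nd2 (1195 ± 48.3 to 744 ± 26.6 TPM) and mt-Nd6 (1466 ± 127 to 839.7 ± 38.2 TPM). Reads of such genes may be shared with nuclear copies, which was not measured here, so the values are uncertain. Mitochondrial mRNAs together took 4.47%, 4.56% and 4.25% of all TPM with PBS and 3.75%, 3.88% and 4.07% with lysine. Mitochondrial ribosomal RNA rose, mt-Rnr1 from 590.4 ± 20.4 to 2780.4 ± 509 TPM and mt-Rnr2 from 457 ± 34.6 to 2156 ± 506 TPM (adjusted p = 6.27e-05 and adjusted p = 0.000144).

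Markers of conventional dendritic cells rose in 3, fell in 2 and did not pass in 6 of 11 cases, the same adjusted over the list alone (camera adjusted p = 0.604). Their median was 0.058, and -0.057 under quantile normalization. Without PBS replicate 1 or 3 or lysine replicate 1, 1 was called lower. The integrin gene Itgax, which encodes CD11c, was at 364 ± 19.4 TPM with PBS and 378 ± 6.54 TPM with lysine (adjusted p = 0.399). Of 14 macrophage markers 6 fell and 0 rose (median log2 fold change -0.47, camera adjusted p = 0.118), and of 8 monocyte markers 4 fell and 0 rose (-0.79, adjusted p = 0.118). The most abundant of these did not pass, Trem2 at 724 ± 38.9 TPM with PBS and 727 ± 131 TPM with lysine and Chil3 at 21815 ± 4677 TPM with PBS and 26800.1 ± 5257 TPM with lysine (adjusted p = 0.957 and adjusted p = 0.264). Chil3 was lowest in replicate 3 of both groups, at 16415 TPM with PBS and 20735 TPM with lysine. Its rise passed only with the replicate block (limma adjusted p = 0.00176). Without PBS replicate 3 or lysine replicate 3, 1 macrophage marker was called higher, as with median-of-ratios scaling (1 higher, 6 lower) and quantile normalization (1 higher, 8 lower). Counts adjusted over each of these lists alone were the same.

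Of 7 neutrophil markers 2 fell and 0 rose (camera adjusted p = 0.263), with Mmp8 at 266 ± 27.6 TPM with PBS and 228 ± 37.1 TPM with lysine (adjusted p = 0.172), which passed without lysine replicate 3 (adjusted p = 0.0187) and under quantile normalization (adjusted p = 0.042). The count was 1 without lysine replicate 1 or 2. Of 8 T and NK cell markers 1 fell, Gzma (21.5 ± 9.84 to 4.43 ± 4.30 TPM; adjusted p = 0.0129), and the list did not pass (camera adjusted p = 0.263); 2 fell without PBS replicate 2 and 4 without lysine replicate 3. Of 7 osteoclast markers 2 rose and 3 fell (camera adjusted p = 0.89), and 1 fell without lysine replicate 1 or 2. The median of the osteoclast list was -0.26 and camera's direction was down, while that of fry was up (adjusted p = 0.0412). Atp6v0d2, a subunit of the lysosomal proton pump that the lysosome list also holds, rose from 228 ± 14.7 to 578 ± 51.7 TPM. Adjusted over the list alone, the counts of these lists were the same.

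Lists with fewer than 5 tested members had no list test. Of 3 markers of plasmacytoid dendritic cells 1 rose and 1 fell, the interferon-induced Bst2 (184 ± 4.06 to 109.9 ± 2.45 TPM). Of 3 mast cell and basophil markers 1 fell, and Gata2 did not pass (adjusted p = 0.119), except without lysine replicate 1 (adjusted p = 0.0168), where 2 markers fell. Of 4 eosinophil markers 1 fell, but 0 adjusted over the list alone and 0 without PBS replicate 1, 2 or 3 or lysine replicate 1 or 2. Siglecf was at 8.04 ± 3.53 TPM with PBS and 8.18 ± 0.776 TPM with lysine (adjusted p = 0.795). Of 2 erythroid markers Car2 rose from 56.3 ± 7.40 to 88.6 ± 22.5 TPM (adjusted p = 0.0368), a call lost in 6 alternatives (adjusted p from 0.063 to 0.109), 4 of them without PBS replicate 2 (0.109) or 3 (0.0901) or lysine replicate 1 (0.104) or 2 (0.106). Without lysine replicate 3, 2 were called higher. The 1 stromal marker tested, Acta2, fell from 2.08 ± 0.411 to 0.633 ± 0.147 TPM. Of 2 B cell markers 0 passed, with Ighm at 2.30 ± 1.79 TPM with PBS and 2.08 ± 1.72 TPM with lysine (adjusted p = 0.87). Apart from the eosinophil list, counts adjusted over the list alone were the same.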

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

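Calls were compared with those of the limma test on log2(TPM + 1), which gave 6904 changed genes. In no alternative did a gene called there take the opposite sign. With a pseudocount of 0.1 there were 6842 changed genes, and 2246 at least 2-fold against 1633. With no filter beyond a value above 0, 6472 of 26231 tested genes changed. Among the alternatives added after seeing the data, there were 7033 with median-of-ratios scaling, 7020 with quantile normalization, 6412 after rescaling to protein-coding nuclear genes, 5742 with a filter of 5 TPM and 6839 without the trend. The share of changed genes that were higher was 46.8%, and 50.9% under median-of-ratios scaling.

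Leaving out each sample in turn gave 5851 to 6969 changed genes, 2747 to 3180 higher, 3082 to 3789 lower, 1568 to 1789 changed at least 2-fold, and 10 to 12 lists that passed camera.

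With a replicate block, which pairs the samples by number, 7339 genes changed (3396 higher and 3943 lower, 1659 at least 2-fold), 6664 of them shared, and 13 lists passed. Among the genes and lists named, Chil3 (adjusted p = 0.00176), Mmp8 (0.0123), the T and NK cell list (0.0285) and the NF-kB list (0.0407) passed with the block and not without it. Counts of lower members moved from 2 to 6 for MHC class II, 1 to 6 for T and NK cell, 4 to 9 for ribosomal protein, 2 to 4 for neutrophil, 3 to 5 for maturation, 1 to 2 for ATF4, 0 to 1 for B cell and 1 to 0 for eosinophil genes. Those of higher members moved from 1 to 4 for LXR, 2 to 4 for oxidative phosphorylation, 0 to 3 for ribosomal protein, 1 to 2 for MHC class I, 0 to 2 for macrophage and 0 to 1 for monocyte genes. Deviations from the group mean of samples with the same number correlated at 0.171, 0.092 and 0.245. Each sample correlated best with its own number, but a correlation was under 0.1, so the numbers were not taken as pairing. The second principal component set replicate 3 of both groups apart, at -19.5 with PBS and -27.8 with lysine. The other samples lay at 8.84 to 14.8, so a shared source or batch of the samples numbered 3 stays possible.

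The list calls depended most on the test. Of 29 lists, 11 passed camera at the preset correlation, 0 with an estimated correlation and 22 with fry. With fry the cholesterol list did not pass (adjusted p = 0.0676). Intended tests that need read counts, namely other count scalings, count filters and a second count-based test, were not run because the deposited table holds no counts.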

Other observations

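Gene families were searched after the results were seen, by shared symbol stem, or by description for tubulins and aminoacyl-tRNA synthetases. Some of their genes are also in the fixed lists. Of 186 families 11 passed camera, though 0 did with an estimated correlation (adjusted p = 0.845). Alpha and beta tubulin genes, the subunits of microtubules, fell in 12 of 13 cases (camera adjusted p = 8.39e-05). The largest falls were those of Tubb2a (-2.79), Tubb6 (-2.07), Tubb5 (-2.02) and Tuba1b (-2.00), given as log2 fold changes, and Tubb1 rose (0.74, adjusted p = 0.0197). Subunits of the 20S proteasome fell in 9 of 10 cases for the stem Psmb (adjusted p = 0.0436) and 7 of 8 for Psma, and mitochondrial ribosomal protein genes of the stem Mrpl in 25 of 50, with 4 higher. Histone lysine demethylases of the stem Kdm rose in 10 of 18 cases and fell in 0 (adjusted p = 0.0474), led by Kdm6b at 7.50 ± 0.514 to 52.4 ± 4.60 TPM (adjusted p = 1.39e-05). Chromatin remodellers of the stem Chd rose in 8 of 10 and fell in 1 (0 under the other scalings), with Chd2 from 21.5 ± 1.07 to 82.9 ± 5.19 TPM. The medians of these families kept their sign under the other scalings.

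Cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids and include members of the ATF4 list and Kars of the cationic amino acid list, rose in 10 and fell in 6 of 20 cases (camera adjusted p = 0.503), and the mitochondrial ones rose in 3 and fell in 7 of 17 (adjusted p = 0.583). Aars (1.59), Yars (1.40) and Cars (1.25) rose, while Kars, the lysine enzyme, fell (-0.66, adjusted p = 0.000388), as did Qars (-0.91), all given as log2 fold changes and chosen after their values were seen.

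All patterns weighed here were picked after the results were seen, and of their tests the split of the samples, the separate RNA classes, the share of short RNAs and the comparison of marker and interferon genes were also chosen then. Of the 10 ways to split the 6 libraries into 3 and 3, the true grouping gave 6904 changed genes and no other split gave more than 3. Every other split mixes PBS and lysine samples within its groups, so the difference between them adds to the spread and keeps calls few. The contrast is therefore no measure of false calls. With 10 splits the share that reaches the true value cannot be under 0.05; 1 split, the true one, reached it. Addition of 18 mM solute raises osmolarity as well as lysine, and no sample with another solute was analysed here, so those causes could not be separated. The hypertonic stress list went both ways, with 5 of 15 higher and 5 lower (camera adjusted p = 0.69), which does not decide between them.

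Several non-coding RNAs without a poly(A) tail were higher with lysine, Rpph1 by 2.97 on the log2 scale, the Rmrp model listed in all samples by 2.53 and the abundant Metazoa_SRP models by 2.35. Metazoa_SRP models of low abundance did not pass (limma adjusted p = 0.089 and 0.509). If the lysine libraries held more RNA without a tail, other such classes should be higher too, and the median log2 fold change of 20 histone and small nuclear, nucleolar and Cajal body RNAs was 0.387 (95% bootstrap interval 0.034 to 1.47), with 0.67 (0.25 to 1.65) for 10 histones and 0.062 (-1.36 to 1.93) for the 10 others. Noise of short gene models would make short RNAs split evenly. Of 42 tested, 12 were higher and 4 lower, but the 12 include those that prompted the pattern. Models with the same TPM in every sample, as for Metazoa_SRP and U2, were each counted, so these counts are not of independent RNAs. Without all models of the symbols that prompted it, a 7SK model that fell included, 25% of 4 were higher, a share that this removal lowers, so neither share decides. Of the 7SK models, the most abundant rose (log2 fold change 2.18, adjusted p = 0.000102), as did another (1.11, adjusted p = 0.0426). A less abundant model fell (-1.48, adjusted p = 0.0338), and the others did not pass. Rpph1 lay at 13.63 to 23.29 TPM with PBS and 101.63 to 187.9 TPM with lysine. The abundant Metazoa_SRP models lay at 137.9 to 200.79 and 746.03 to 1003.36 TPM. These rises exceeded the spread within groups, but the models prompted the pattern and cannot test it. Mitochondrial ribosomal RNA, not among the short models, rose from 991.52 to 1092.06 TPM with PBS to 3810.5 to 5781.21 TPM with lysine. For the short models as a class, a difference in RNA selection or degradation and noise both stay open. A change in transcription or stability caused by lysine was not tested.

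The fall of interferon-response genes could come from fewer monocytes or macrophages in the lysine cultures, whose markers should then fall as far. The median of 22 such markers was -0.59. It lay 0.879 above that of the interferon genes (95% bootstrap interval of the difference 0.417 to 1.42), so these markers did not fall as far. The interferon list was picked after it was seen to be the lowest, and the bootstrap treats its genes as independent. The comparison therefore does not exclude a change in cells, and markers of other cell types were not compared. After a trend of fold change with transcript length and GC content was removed, the interferon median was -1.39 (-1.87 to -1.04), which excludes that trend as the whole cause. Lower interferon signalling with lysine was not tested against a measure of interferon.

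The fall of tubulin genes could arise if reads moved between near-identical paralogs, but the summed TPM of all 21 alpha and beta tubulin models fell from 2025 ± 33.7 to 533 ± 17.9 TPM, a log2 ratio of -1.93. After the trend with transcript length and GC content was removed, the median of 13 tubulin genes was -1.49 (95% bootstrap interval -1.74 to -0.82). Neither explanation accounts for the whole fall. Tubulin mRNAs are degraded when free tubulin rises, and that cause was not tested here.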
